A study of Mus musculus with 8 samples.

How the data were processed

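RNA of mouse ileum had been sequenced on an Ion Proton instrument as 8 libraries in 4 groups, with 2 libraries per group and 3 animals pooled per library, per the labels and the series description. The deposited files list, per library and gene, an estimated number of reads and an RPKM value, per the file headers. The authors' estimated counts are not scaled and carry fractions, and they were rounded to whole numbers before testing. The RPKM values were divided by gene length and library total by the authors, and they served in 1 alternative only, as log2 of the value plus 1. The genome build was mm10, per the submitters' processing notes. The aligner, its settings and the estimator of reads are not given in the sources used here. The deposited files list no gene at 0 reads, and a gene absent from a file was entered at 0, though a failed estimate would look the same. A gene absent from every library of a group is called not listed, with no fold change given.

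Each library listed 20384 to 21438 genes, 25333 in any library and 17245 in all 8. Library totals lay between 20180571 and 21513950 estimated reads, and 3 reads correspond to 0.139 to 0.149 CPM. The 10 genes with most reads took 5.85% to 6.57% of the reads, and 0% were in listed mitochondrial genes. Symbols and mm10 positions came from the RefSeq gene table of the same assembly: 23814 genes were matched by gene number, 4 by accession and 1515 stayed unnamed. Near-identical copies and close relatives, such as Hba-a1 and Hba-a2, Hbb-b1 and Hbb-b2, Hspa1a and Hspa1b, the Gsdmc genes, Saa1 and Saa2 and the Defa genes, can exchange reads in the estimates, and single members are uncertain. Whether the related Mcpt genes do so was not tested.

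The groups, comparisons, tests, gene lists and naming rule were fixed before the data were examined. Some single genes are not reported here. Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, a filter on expression (minimum count 10, minimum total 15), 1 mean per group over all 8 libraries and a quasi-likelihood F test with 4 residual degrees of freedom. Over the 16899 genes tested, p-values were adjusted by Benjamini-Hochberg and called under 0.05. Fold changes carry the model's standard error. The 38 gene lists, each with 5 or more tested members, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists, and again with a correlation estimated per list and with fry. The run with an estimated correlation also refers its statistic to the 4 residual degrees of freedom, far fewer than the preset run uses. A list can thus lose its call there without correlated members. In Sensitized against Naive the retinoic acid metabolism list had an estimated correlation of 0.00974, while its camera p went from 0.0352 to 0.102. Camera asks whether the members of a list moved more than other genes, while fry asks whether they moved on balance in 1 direction. DESeq2 1.42.0 was run as another test. Intervals on ratios of few reads are exact, cover 95% and describe counting error alone.

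The genes named were, in Sensitized against Naive and in each vaccinated group against Sensitized, the 6 largest called changes in each direction whose libraries did not overlap between groups, up to 3 members with the smallest p of each list called and of the regulatory T cell, tolerogenic dendritic cell, mast cell and type 2 cytokine lists, and 12 tested marker genes of tolerance and allergy. In the other comparisons they were the 3 largest called changes in each direction. Unnamed gene models, immunoglobulin and T cell receptor segments and pseudogenes were left out of the choice by size, and places without a called gene would be filled by the smallest unadjusted p. Other names are given where a count is small, and the text says that they were chosen after their values were seen.

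Each step was tested on simulated counts, with 1 mean per gene over all groups, the library sizes and each real group's spread. In each of 5 data sets 200 genes were changed, over 16531 to 16576 genes in Sensitized against Naive. In that comparison edgeR recovered 20.6% of 1.5-fold, 59.4% of 2-fold and 79.7% of 4-fold changes, and 180 of its 808 calls were of unchanged genes. Of DESeq2's calls, 50.5% were of unchanged genes there, 22.1% in P-MEM49 against Sensitized and 24.7% in T-MEM49 against Sensitized. With no effect simulated, 20 data sets gave at most 1 edgeR call each in Sensitized against Naive. A list shifted by 1 log2 was called in 5 of 5 data sets in each of the 3 comparisons, and 0 of 181 other lists were called by camera. Genes were drawn independently there, so list members were not correlated. In the real data the estimated correlation was 0.896 in the B cell list in Sensitized against Naive. The simulation thus does not measure false calls of correlated lists.

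Alternatives fixed in advance were DESeq2's size factors, the DESeq2 test, no filter, the replicate number as a block, a fit of the compared groups alone, a minimum log2 fold change of 1, limma on RPKM, other list tests and leaving out each library in turn. A term for Naive replicate 2 and Sensitized replicate 2, a restriction to genes listed in every library and a limma voom fit with a weight per group were added after the data were seen. A fit without 1 library takes the spread of the remaining lone library from the other groups. Since the pairs differ in spread, a call lost or gained there need not mean that the effect changed. In P-MEM49 against Sensitized the log2 fold change of Abcc2 ranged over -0.71 to -0.69 with a library left out, and that of Saa1 over -2.81 to -1.26.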

Results

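Ileum tissue of BALB/c mice, an inbred strain, was profiled by RNA sequencing in 4 groups of 2 libraries, each library made from the pooled RNA of 3 animals. Naive mice were not sensitized. Sensitized mice received shrimp tropomyosin, the major shellfish allergen, with a sham treatment, PBS or mock plasmid. The labels do not say which Sensitized library received which, so the 2 may differ in treatment. P-MEM49 mice were given a DNA vaccine encoding the hypoallergen MEM49 in the skin before sensitization, and T-MEM49 mice received it after sensitization. Tissue was taken within 24 h of a challenge by the gastric route. The deposited estimated reads per library summed to between 20180571 and 21513950, and 16899 genes entered the tests. As the series text reads, the pools are separate samples of different animals, so a p-value here measures the spread between pools and not between mice. Normalised read counts (CPM) are means ± SD over the 2 libraries of a group (n = 2), and log2 fold changes carry their standard error (SE).

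The pairs of libraries differed in tightness, with a biological coefficient of variation of 13.2% in Naive, 21.1% in Sensitized, 6.84% in P-MEM49 and 7.39% in T-MEM49. Within each pair the median chi-square per gene lay between 1.43 and 4.45, against 0.455 from sampling alone. Library preparation adds to this spread too, so it does not show that the pools differ, and the 2 libraries of a group were treated as separate samples on the series text alone. Naive replicate 2 and Sensitized replicate 2 stood apart from the other 6 libraries in 87 of 12949 genes, and the next pair of libraries from different groups did so in 25. Lars2, a mitochondrial leucyl-tRNA synthetase gene, read 722 and 490 CPM in these 2 libraries and 103 to 229 CPM in the others.

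Comparing Sensitized with Naive ileum asks what allergic sensitization changed in the tissue. Reg3g, which encodes a bactericidal lectin of the gut lining (Entrez gene 19695, chromosome 6, 78466269 to 78468874; all positions on mm10), rose from 1461 ± 174 to 6037 ± 454 CPM, a log2 fold change of 2.05 ± 0.10 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.55e-04). Smooth muscle genes rose with it: Actg2, the smooth muscle gamma actin (Entrez gene 11468, chromosome 6, 83512909 to 83536251), went from 103 ± 14.1 to 366 ± 112 CPM (log2 fold change 1.83 ± 0.19, edgeR adjusted p = 0.00235). Interferon gamma response genes fell, among them Gbp2, an interferon-induced GTPase (Entrez gene 14469, chromosome 3, 142620663 to 142638008), from 169 ± 14.1 to 68.6 ± 6.03 CPM (log2 fold change -1.30 ± 0.099, edgeR adjusted p = 7.31e-04). Ido1, the tryptophan-degrading enzyme linked to tolerogenic dendritic cells (Entrez gene 15930, chromosome 8, 24584133 to 24596952), fell from 252 ± 9.24 to 95.8 ± 0.365 CPM (log2 fold change -1.39 ± 0.084, edgeR adjusted p = 2.81e-04).

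The Paneth cell and antimicrobial list rose, with 14 of its 22 tested members higher (16 adjusted over the list alone) and a median log2 fold change of 0.85 (camera adjusted p = 1.91e-12, adjusted p = 0.119 with an estimated correlation). Beside Reg3g, its close relative Reg3b rose by 1.69 ± 0.18 and the lysozyme gene Lyz1 by 0.87 ± 0.086 on the log2 scale. In the smooth muscle list 17 of its 20 tested members were higher (20 adjusted over the list alone), with a median of 1.17 (camera adjusted p = 9.95e-17, adjusted p = 0.328 with an estimated correlation). Desmin, Des, rose by 1.28 ± 0.13 and Csrp1 by 1.18 ± 0.16. The enteric nervous system list rose as well, with a median of 0.99 and 3 of its 16 tested members higher, 9 adjusted over the list alone (camera adjusted p = 1.74e-05, adjusted p = 0.348 with an estimated correlation). Its 3 higher members were Nos1, the neuronal nitric oxide synthase, the neuronal filament gene Prph and the synaptic gene Snap25, and each lost its call with either Naive library left out (edgeR adjusted p up to 0.158, 0.140 and 0.128). Csrp1 lost its call without Naive replicate 1 (edgeR adjusted p = 0.0523). Within the Sensitized pair, the nerve list was 0.62 and the smooth muscle list 0.64 log2 higher (medians) in replicate 1 than in replicate 2.

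In the Th1 and interferon gamma list 16 of its 27 tested members fell and 1 rose, the cytokine gene Il18 (21 lower and 1 higher adjusted over the list alone), with a median of -0.74 (camera adjusted p = 1.19e-14, adjusted p = 0.119 with an estimated correlation). The immunoproteasome genes Psmb9 (-1.23 ± 0.094) and Psmb8 (-0.89 ± 0.087) were among those that fell. The macrophage list fell, with 6 of its 18 tested members lower, 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.61e-04, adjusted p = 0.328 with an estimated correlation). It included the complement gene C1qb (-0.77 ± 0.13) and the fractalkine receptor gene Cx3cr1 (-0.76 ± 0.13). The intraepithelial cytotoxic lymphocyte list fell, with 2 of its 19 tested members lower, the granzyme gene Gzmb (-0.76 ± 0.084) and the integrin gene Itgae (-0.52 ± 0.087), and 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.45e-04, adjusted p = 0.328 with an estimated correlation). In the list of all dendritic cell genes 1 of its 17 tested members fell, Irf8 (-0.80 ± 0.075), a transcription factor of dendritic cells, and 1 adjusted over the list alone (camera adjusted p = 0.0313, adjusted p = 0.328 with an estimated correlation). Without Naive replicate 2, C1qb did not pass, and with either Naive library left out Cx3cr1 and Itgae did not (edgeR adjusted p up to 0.0829, 0.0819 and 0.0750). Leaving out Sensitized replicate 1 or Naive replicate 2 ended the dendritic cell list's call (camera adjusted p = 0.342 and 0.0857).

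The B cell and germinal centre list rose with a median of 1.48, and 5 of its 29 tested members were higher, 21 adjusted over the list alone (camera adjusted p = 2.38e-08, adjusted p = 0.428 with an estimated correlation). Its level was carried by 1 library: the median gene was -1.71 log2 in Sensitized replicate 1 relative to replicate 2, and Pax5, the B cell identity factor, read 30.8 ± 26.0 CPM against 6.55 ± 1.36 in Naive. The list passed with either of the 2 Sensitized libraries left out, while its called members Pax5 and Fcmr did not pass with either Naive library left out (edgeR adjusted p up to 0.203 and 0.176). Mef2b and Gcsam, germinal centre genes, were also called. In the enterocyte list 7 of its 28 tested members were higher and 1 lower, the bile acid binding gene Fabp6 (9 and 3 adjusted over the list alone; camera adjusted p = 0.00293, adjusted p = 0.512 with an estimated correlation), led by the glucose transporter gene Slc2a2 (0.222 ± 0.183 to 12.2 ± 0.751 CPM), the fatty acid binding protein gene Fabp1 (0.670 ± 0.0979 to 10.6 ± 3.41 CPM) and the trehalase gene Treh (1.30 ± 0.087 log2). Without Sensitized replicate 1 the enterocyte list did not pass (camera adjusted p = 0.354). The fixed proximal small intestine list, which shares Lct and Fabp1 with the enterocyte list, did not pass by camera. Of its 12 tested members 5 were called, and 8 had an unadjusted edgeR p under 0.05, 5 higher and 3 lower. Whether the groups' tissue pieces came from different stretches of the gut was not tested. The fatty acid oxidation list rose with 6 of its 23 tested members higher, 10 adjusted over the list alone (camera adjusted p = 0.00132, adjusted p = 0.363 with an estimated correlation), including Acadl (0.60 ± 0.079), an acyl-CoA dehydrogenase gene. The cholesterol synthesis list fell with 4 of its 22 tested members lower, 5 adjusted over the list alone (camera adjusted p = 0.00132, adjusted p = 0.328 with an estimated correlation), including the enzyme genes Lss, Fdps and Mvd. Lss and Fdps did not pass with either Naive library left out (edgeR adjusted p up to 0.0735 and 0.102). Il18, Mef2b, Gcsam, Fabp6 and Mvd lie outside the fixed naming rule and were chosen after their values were seen.

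In the crypt stem and proliferation list 1 of its 30 tested members fell, Cdca7 (-0.51 ± 0.10), with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.59e-05, adjusted p = 0.328 with an estimated correlation). The adipose and blood lists were fixed as carry-over lists, for fat and blood left in the tissue pieces. The adipose list rose with 2 of its 13 tested members higher, Fabp4 (1.65 ± 0.30) and Cidec (0.64 ± 0.14), and 10 adjusted over the list alone (camera adjusted p = 1.66e-04, adjusted p = 0.395 with an estimated correlation). Without Sensitized replicate 2 the list did not pass (camera adjusted p = 0.122). Cdca7, Fabp4 and Cidec each lost their calls with either Naive library left out, Cdca7 also without Sensitized replicate 1 and Cidec without Sensitized replicate 2 (edgeR adjusted p up to 0.117, 0.120 and 0.150). For the blood list, which rose with a median of 0.72 (camera adjusted p = 0.0488, adjusted p = 0.363 with an estimated correlation), 0 of its 6 tested members passed in edgeR over all genes, with 3 higher at an unadjusted p under 0.05. Of these 6 genes 1 passed in DESeq2 and 3 were higher adjusted over the list alone. The blood list did not pass without Naive replicate 1 (camera adjusted p = 0.102) or Sensitized replicate 2 (camera adjusted p = 0.215).

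The lists closest to allergy and tolerance did not pass. Camera adjusted p was 0.307 for the regulatory T cell list, 0.987 for the tolerogenic dendritic cell list, 0.939 for the mast cell list and 0.987 for the type 2 cytokine list. In the regulatory T cell list 1 of 26 members rose and 3 fell, with the same counts adjusted over the list alone. The riser was the ecto-nucleotidase gene Nt5e (0.88 ± 0.18), and Gzmb, Itgae and Socs1 fell, Socs1 being chosen for naming after its value was seen. In the tolerogenic dendritic cell list 2 of 32 rose and 3 fell (3 and 3 adjusted over the list alone), with Socs3, a brake on cytokine signalling, at 0.96 ± 0.13 and Ido1 at -1.39 ± 0.084. The retinal dehydrogenase gene Aldh1a1, named after its value was seen, was the other riser, and Itgae and Irf8 fell with Ido1. The median, mean and test of 3 of these lists differed in sign: the regulatory T cell list had a median of -0.059 and a mean of 0.011, the tolerogenic dendritic cell list 0.055 and 0.0048, and the mast cell list 0.24 and -0.14, and the test's direction was lower for each. Of 11 mast cell genes 1 fell (2 adjusted over the list alone), the mucosal mast cell protease gene Mcpt2 (log2 fold change -1.18 ± 0.28, edgeR adjusted p = 0.0448). With either Naive library or Sensitized replicate 1 left out, Mcpt2 did not pass (edgeR adjusted p up to 0.193), and neither Nt5e with either Naive library left out (up to 0.137) nor Socs3 without Naive replicate 2 (0.0564) did. Mcpt1, a protease gene related to Mcpt2, read 14.7 ± 0.0821 CPM in Naive and 13.5 ± 7.19 CPM in Sensitized (edgeR adjusted p = 0.851). In the type 2 cytokine list 0 of 19 members passed in edgeR, 3 had an unadjusted p under 0.05, 1 passed in DESeq2 and 0 passed adjusted over the list alone. Il4 and Il13, the main type 2 cytokine genes, lay below the expression filter. Foxp3, the regulatory T cell factor, read 2.90 ± 0.573 CPM in Naive and 2.73 ± 0.287 CPM in Sensitized (edgeR adjusted p = 0.893), and the same test gave 0.257 for Il10, 0.584 for Tgfb1, 0.885 for Il2ra, 0.741 for Ctla4, 0.292 for Aldh1a2, 0.108 for Cd274 and 0.346 for Cpa3.

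Among the genes with the largest changes by the fixed rule, Lct, Pcdh15, Tenm2, Zfp97, Cyp2d12 and Fmn2 were not listed in either Naive library. A gene not listed was entered at 0 reads, and whether it had no reads or a failed estimate is not known, here and for the unlisted genes below. Lct, the lactase gene, read 1.10 and 7.67 CPM in the Sensitized libraries, and Zfp97, a zinc finger gene, 1.87 and 1.91 CPM. In the other direction, Cntnap5b and the lactoperoxidase gene Lpo were not listed in either Sensitized library and read 0.578 ± 0.0329 and 0.514 ± 0.335 CPM in Naive. Car1, a carbonic anhydrase gene, fell from 69.6 ± 12.1 to 6.31 ± 6.29 CPM (-3.46 ± 0.52 log2), and the lipid transporter gene Abca12 (-2.54 ± 0.42) and the endocrine cell factor Pax4 (-3.81 ± 0.67) fell as well. Without Naive replicate 1 Car1 and Abca12 did not pass, and with either Naive library left out Pax4 did not (edgeR adjusted p up to 0.0523, 0.0778 and 0.0826). The water channel gene Aqp8 had 23 reads in Naive and 1 in Sensitized, a ratio of 23.1 with a 95% exact counting interval of 3.75 to 953. With either Naive library left out, Aqp8, Lct, Pcdh15, Tenm2, Cyp2d12, Fmn2, Cntnap5b and Lpo did not pass (edgeR adjusted p up to 0.147, 0.163, 0.128, 0.0982, 0.0667, 0.0605, 0.160 and 0.165), while Zfp97 did.

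Over all genes, 1162 of 16899 passed edgeR's test, 684 higher and 478 lower in Sensitized. This number carries more false calls than its threshold states: in 5 data sets simulated with the spread of each pair, 22.3% of edgeR's calls fell on genes that had not been changed, against 9.23% for limma voom with a weight per group, a test added after the data were seen that called 520 genes, 517 of them shared. With only the compared groups in the fit the count was 67, with no low-count filter 727, by DESeq2 1418 and with a term for Naive replicate 2 and Sensitized replicate 2, added after the data were seen, 1912. Without Naive replicate 1 the count was 281 and without Naive replicate 2 it was 290. Of the 48 named genes that passed, 19 passed without Naive replicate 1, 20 without Naive replicate 2, 41 without Sensitized replicate 1 and 44 without Sensitized replicate 2, and 17 passed in each of these, among them Reg3g, Reg3b, Actg2, Des, Gbp2, Psmb8, Psmb9, Ido1, Gzmb, Irf8, Slc2a2, Fabp1, Treh, Acadl, Lyz1 and Zfp97. Zfp97 was not listed in either Naive library, so its passing does not tell a change from a failed estimate. By camera 14 of 38 lists passed, 0 did with an estimated correlation (3 at an unadjusted p under 0.05), and fry called 20.

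**Figure D1:**
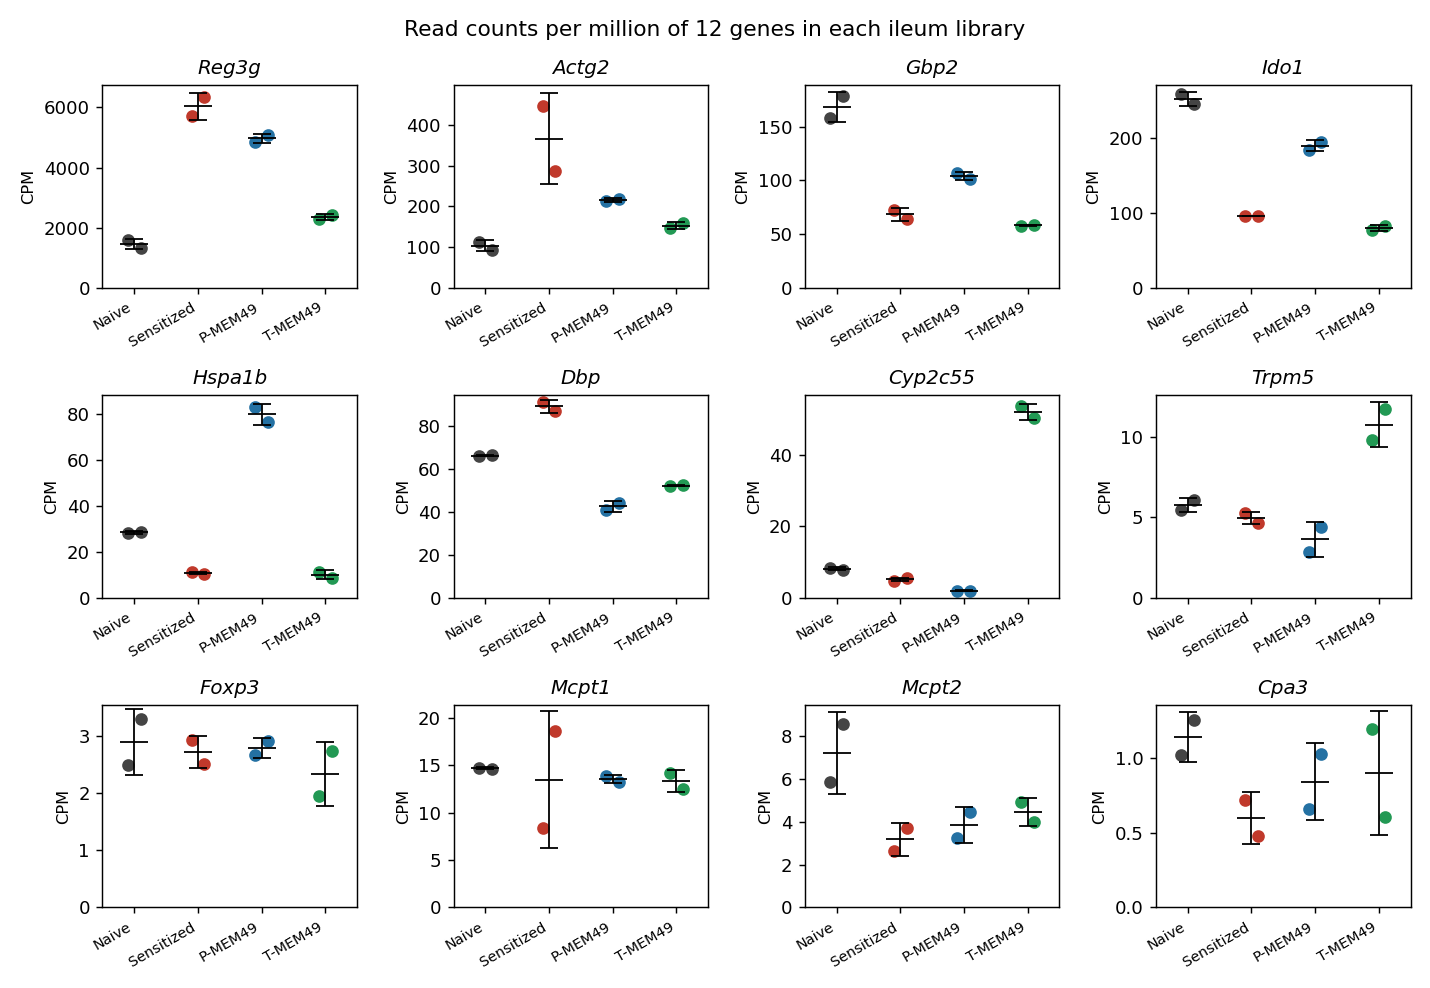
Each panel plots the normalised read count (CPM, vertical axis) of 1 gene in the 8 ileum libraries by group, with points for libraries and lines for the mean ± SD of the 2 libraries. Reg3g and Actg2 were highest in Sensitized, Hspa1b stood at 79.9 ± 4.59 CPM in P-MEM49 and Cyp2c55 at 51.8 ± 2.27 CPM in T-MEM49, while Foxp3 lay under 4 CPM in every library.

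Comparing P-MEM49 with Sensitized ileum asks what vaccination before sensitization changed. Heat shock chaperone genes rose: Hspa1b (Entrez gene 15511, chromosome 17, 34956429 to 34959238) went from 10.7 ± 0.437 to 79.9 ± 4.59 CPM, a log2 fold change of 2.89 ± 0.14 (edgeR quasi-likelihood test, adjusted p = 9.89e-05), and Hsph1 (Entrez gene 15505, chromosome 5, 149616843 to 149636498) from 22.5 ± 1.35 to 123 ± 0.824 CPM (2.46 ± 0.12, edgeR adjusted p = 9.89e-05). Hspa1a, a near-identical neighbour of Hspa1b whose reads the deposited estimates can split between the copies, stood at 2.69 ± 0.15. Hspa1b read 28.4 CPM in Naive. Ido1 rose from 95.8 ± 0.365 to 189 ± 7.42 CPM (log2 fold change 0.98 ± 0.083, edgeR adjusted p = 0.00192) and Gzmb by 0.92 ± 0.084 (edgeR adjusted p = 0.00237), against 252 ± 9.24 and 176 ± 4.94 CPM in Naive. Cyp3a25, a drug-metabolizing cytochrome P450 gene, fell from 51.0 ± 3.92 to 20.3 ± 0.152 CPM (log2 fold change -1.33 ± 0.10, edgeR adjusted p = 0.00183).

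The immediate early and handling stress list rose with 5 of its 20 tested members higher, 6 adjusted over the list alone (camera adjusted p = 4.94e-05, adjusted p = 0.515 with an estimated correlation). They were Hspa1a, Hspa1b, Hsph1, the cochaperone gene Dnajb1 and the stress factor Atf3, the last 2 named after their values were seen. The Th1 and interferon gamma list rose with a median of 0.25 and 1 of its 27 tested members higher, Gbp2 (0.60 ± 0.099), and 9 higher adjusted over the list alone (camera adjusted p = 2.33e-04, adjusted p = 0.515 with an estimated correlation). The xenobiotic metabolism list fell with 3 of its 22 tested members lower, 7 adjusted over the list alone (camera adjusted p = 0.00259, adjusted p = 0.515 with an estimated correlation): Cyp3a25, Cyp2c55 (-1.37 ± 0.15), another P450 gene, and the export pump gene Abcc2 (-0.70 ± 0.092). With either P-MEM49 library left out Gbp2, Cyp2c55, Abcc2 and Des did not pass. With each library of the 2 groups left out in turn, their log2 fold changes kept their sign. They ranged over 0.52 to 0.70, -1.47 to -1.26, -0.71 to -0.69 and -1.06 to -0.61. In the smooth muscle list 1 of its 20 tested members fell, Des (-0.85 ± 0.13), and 16 adjusted over the list alone, with a median of -0.61 (camera adjusted p = 4.28e-11, adjusted p = 0.689 with an estimated correlation). The enteric nervous system list fell with a median of -0.77 (camera adjusted p = 4.94e-05, adjusted p = 0.731 with an estimated correlation), while 0 of its 16 tested members passed in edgeR over all genes, with 10 lower at an unadjusted p under 0.05. Of these 16 genes 0 passed in DESeq2 and 8 were lower adjusted over the list alone. Without Sensitized replicate 1 the nerve list did not pass (camera adjusted p = 0.123).

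The blood list fell with a median of -1.0 (camera adjusted p = 0.00146, adjusted p = 0.515 with an estimated correlation), while 0 of its 6 tested members passed in edgeR over all genes, with 4 lower at an unadjusted p under 0.05. Of these 6 genes 2 passed in DESeq2 and 4 were lower adjusted over the list alone. Slight rises of the macrophage, crypt and plasma cell lists rested on Sensitized replicate 1. The macrophage list had a median of 0.21 (camera adjusted p = 0.00259, adjusted p = 0.689 with an estimated correlation) and 0 of its 18 tested members passed in edgeR over all genes, with 4 higher at an unadjusted p under 0.05. Of these 18 genes 0 passed in DESeq2 and 0 were higher adjusted over the list alone. Its camera adjusted p was 0.128 without that library. For the crypt stem and proliferation list the median was 0.17 (camera adjusted p = 0.0146, adjusted p = 0.794 with an estimated correlation), 0 of its 30 tested members passed in edgeR over all genes, with 5 higher at an unadjusted p under 0.05. Of these 30 genes 1 passed in DESeq2 and 0 were higher adjusted over the list alone. Camera gave this list 0.882 without Sensitized replicate 1 and 0.0637 without P-MEM49 replicate 1. For the plasma cell list the median was 0.15 (camera adjusted p = 0.0267, adjusted p = 0.794 with an estimated correlation), 0 of its 15 tested members passed in edgeR over all genes, with 2 higher at an unadjusted p under 0.05. Of these 15 genes 0 passed in DESeq2 and 0 were higher adjusted over the list alone. Camera gave the plasma cell list 0.995 without Sensitized replicate 1 and 0.0546 without P-MEM49 replicate 1.

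Regulatory T cell and tolerogenic dendritic cell genes, the subject the series names, did not pass as lists. Camera adjusted p was 0.107 and 0.619 for them, 0.999 for mast cell genes and 0.665 for type 2 cytokine genes. In the regulatory T cell list 1 of 26 members rose, Gzmb, with 2 higher and 1 lower adjusted over the list alone. In the tolerogenic dendritic cell list 1 of 32 rose, Ido1, and 1 fell, Socs3 (-0.85 ± 0.13, edgeR adjusted p up to 0.293 with either P-MEM49 library left out), with 1 higher and 2 lower adjusted over the list alone. Foxp3 read 2.80 ± 0.174 CPM against 2.73 ± 0.287 (edgeR adjusted p = 0.967), and edgeR adjusted p was 0.314 for Il10, 0.731 for Tgfb1, 0.775 for Itgae, 0.999 for Mcpt1, 0.693 for Mcpt2, 0.712 for Cpa3, 0.498 for Il2ra, 0.494 for Ctla4, 0.149 for Aldh1a2 and 0.173 for Cd274. Of the mast cell and type 2 cytokine genes, 0 of 11 and 0 of 19 passed in edgeR, 2 and 0 had an unadjusted p under 0.05, 0 and 0 passed in DESeq2, and 0 and 0 passed adjusted over the list alone.

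The other genes named for size included Tppp, which encodes a tubulin polymerization protein (1.71 ± 0.20 log2), and the interferon-inducible gene Ifi202b (1.72 ± 0.24), both higher. Dmrt3, a transcription factor gene, had 131 reads in P-MEM49 and 3 in Sensitized, a ratio of 43.6 with a 95% exact counting interval of 14.6 to 214. The acute phase gene Saa1 fell from 393 ± 273 to 83.7 ± 0.981 CPM, the class I-like gene H2-M2 from 13.3 ± 1.43 to 3.70 ± 0.209, the potassium channel gene Kcnj13 from 2.66 ± 0.388 to 0.549 ± 0.0196 and the neuronal RNA Bc1 from 41.6 ± 36.3 to 1.43 ± 0.0982. Pclo, a presynaptic scaffold gene, and Zkscan16 were not listed in either P-MEM49 library and read 6.06 ± 2.17 and 1.12 ± 0.0407 CPM in Sensitized.

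Over all genes, 183 passed, 95 higher and 88 lower in P-MEM49. In simulated data edgeR recovered 22.7%, 57.6% and 79.1% of genes changed 1.5-fold, 2-fold and 4-fold, and 6.84% of its calls were of unchanged genes. With only the compared groups in the fit the count was 31, with no low-count filter 101 and by DESeq2 549. The count was 23 without P-MEM49 replicate 1, 24 without P-MEM49 replicate 2, 583 without Sensitized replicate 1 and 578 without Sensitized replicate 2. Of 20 named genes that passed, 7 passed with either P-MEM49 library left out: Hspa1a, Hspa1b, Hsph1, Ido1, Gzmb, Cyp3a25 and H2-M2. For Tppp, Ifi202b, Dmrt3, Kcnj13, Saa1 and Bc1 the edgeR adjusted p with either P-MEM49 library left out reached 0.101, 0.220, 0.0622, 0.275, 0.352 and 0.372. By camera 9 of 38 lists passed, 0 did with an estimated correlation (3 at an unadjusted p under 0.05) and fry called 3. Leaving out Sensitized replicate 2 raised the number of lists to 14.

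Comparing T-MEM49 with Sensitized ileum asks what vaccination after sensitization changed. Cyp2c55, a cytochrome P450 gene (Entrez gene 72082, chromosome 19, 39006940 to 39042690), rose from 5.07 ± 0.510 to 51.8 ± 2.27 CPM, a log2 fold change of 3.35 ± 0.13 (edgeR quasi-likelihood test, adjusted p = 3.38e-05). Car1 (Entrez gene 12346, chromosome 3, 14766214 to 14808365) rose from 6.31 ± 6.29 to 254 ± 6.42 CPM (5.33 ± 0.54, edgeR adjusted p = 0.00901), against 69.6 ± 12.1 CPM in Naive. The gasdermin gene Gsdmc2 (Entrez gene 331063, chromosome 15, 63824328 to 63845193) rose from 3.82 ± 2.01 to 26.7 ± 0.50 CPM (2.80 ± 0.29, edgeR adjusted p = 0.00901). Hemoglobin genes fell, with Hba-a1 (Entrez gene 15122, chromosome 11, 32283672 to 32284486) going from 35.7 ± 9.59 to 1.55 ± 0.172 CPM (-4.52 ± 0.26, edgeR adjusted p = 3.14e-04). They belong to the blood carry-over list, and whether less blood was left in these tissue pieces was not tested. Reg3g fell from 6037 ± 454 to 2360.3 ± 109 CPM (-1.35 ± 0.10, edgeR adjusted p = 0.00160). With either T-MEM49 library left out Car1, Gsdmc2 and Reg3g did not pass (edgeR adjusted p up to 0.148, 0.180 and 0.0643), while Cyp2c55 and Hba-a1 did. Gsdmc2 has near copies beside it, so its share of their reads is uncertain.

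The tuft cell list, genes of the chemosensory cells of the epithelium, rose with a median of 0.95. In it 1 of its 16 tested members was higher, Sh2d6 (3.89 ± 0.60), and 8 adjusted over the list alone (camera adjusted p = 1.15e-07, adjusted p = 0.190 with an estimated correlation). The taste channel gene Trpm5 read 10.8 ± 1.37 CPM against 4.95 ± 0.402 (edgeR adjusted p = 0.0852) and Siglecf 2.65 ± 0.120 against 0.526 ± 0.0708 (edgeR adjusted p = 0.0716). The goblet cell and mucus list rose with a median of 0.12 (camera adjusted p = 0.0234, adjusted p = 0.459 with an estimated correlation), while 0 of its 17 tested members passed in edgeR over all genes, with 3 higher at an unadjusted p under 0.05. Of these 17 genes 0 passed in DESeq2 and 0 were higher adjusted over the list alone. Camera gave it 0.114 without Sensitized replicate 2 and 0.0599 without T-MEM49 replicate 1. In the circadian clock list 2 of its 18 tested members fell, the clock output genes Ciart (-1.70 ± 0.16) and Dbp (-0.77 ± 0.086), and 11 were lower and 2 higher adjusted over the list alone (camera adjusted p = 7.34e-08, adjusted p = 0.190 with an estimated correlation). The blood list fell with 4 of its 6 tested members lower, 5 adjusted over the list alone, and a median of -3.57 (camera adjusted p = 8.91e-13, adjusted p = 0.190 with an estimated correlation). Sh2d6, Ciart and Dbp did not pass with either T-MEM49 library left out, nor did Sh2d6 without Sensitized replicate 1 (edgeR adjusted p up to 0.374, 0.148 and 0.234). Hemoglobin genes exist in near-identical copies, so the split of reads between Hba-a1 and Hba-a2, or Hbb-b1 and Hbb-b2, is uncertain.

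The smooth muscle list fell with 5 of its 20 tested members lower, 20 adjusted over the list alone (camera adjusted p = 6.48e-22, adjusted p = 0.332 with an estimated correlation), Des (-1.05 ± 0.13), the myosin light chain gene Myl9 (-1.24 ± 0.18), Pcp4, Actg2 and the kinase gene Mylk, the last 2 named after their values were seen. With either T-MEM49 library left out Des, Myl9 and Pcp4 did not pass (edgeR adjusted p up to 0.262, 0.399 and 0.385). The enteric nervous system list fell with a median of -0.97 (camera adjusted p = 1.73e-08, adjusted p = 0.437 with an estimated correlation), while 0 of its 16 tested members passed in edgeR over all genes, with 10 lower at an unadjusted p under 0.05. Of these 16 genes 3 passed in DESeq2 and 10 were lower adjusted over the list alone. In the Th17 and IL-22 list 2 of its 17 tested members fell, Reg3g and Saa1 (393 ± 273 to 50.7 ± 1.84 CPM, edgeR adjusted p up to 0.408 with either T-MEM49 library left out), and 6 adjusted over the list alone (camera adjusted p = 0.00129, adjusted p = 0.190 with an estimated correlation). The type I interferon list fell with a median of -0.18 (camera adjusted p = 2.41e-04, adjusted p = 0.459 with an estimated correlation), and 0 of its 29 tested members passed in edgeR over all genes, with 3 lower at an unadjusted p under 0.05. Of these 29 genes 3 passed in DESeq2 and 3 were lower adjusted over the list alone. Without Sensitized replicate 1 its camera adjusted p was 0.218.

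Calls for 3 further lists did not hold without single libraries. The Th1 and interferon gamma list was lower with a median of -0.10 (camera adjusted p = 0.0259, adjusted p = 0.459 with an estimated correlation), 0 of its 27 tested members passed in edgeR over all genes, with 7 lower at an unadjusted p under 0.05. Of these 27 genes 2 passed in DESeq2 and 0 were lower adjusted over the list alone. Camera gave it 0.280 without Sensitized replicate 1 and 0.184 without T-MEM49 replicate 2. For the immediate early and handling stress list the median was -0.14 (camera adjusted p = 0.0408, adjusted p = 0.576 with an estimated correlation), 0 of its 20 tested members passed in edgeR over all genes, with 3 lower at an unadjusted p under 0.05. Of these 20 genes 1 passed in DESeq2 and 1 was lower adjusted over the list alone. Camera gave it 0.592 without Sensitized replicate 2 and 0.400 without T-MEM49 replicate 2. For the inflammation and neutrophil list it was -0.34 (camera adjusted p = 0.0484, adjusted p = 0.437 with an estimated correlation), 0 of its 15 tested members passed in edgeR over all genes, with 3 lower at an unadjusted p under 0.05. Of these 15 genes 0 passed in DESeq2 and 0 were lower adjusted over the list alone. Camera gave it 0.585 and 0.102 without the same 2 libraries.

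Camera adjusted p was 0.514 for the regulatory T cell list, 0.397 for the tolerogenic dendritic cell list, 0.624 for the mast cell list and 0.676 for the type 2 cytokine list. In the tolerogenic dendritic cell list 1 of 32 members fell, the galectin gene Lgals1 (-1.06 ± 0.16), and 1 adjusted over the list alone. Lgals1 did not pass with either T-MEM49 library left out (edgeR adjusted p up to 0.408). The type 2 cytokine list had a median of 0.032 and a mean of -0.042. In the other 3 lists 0 of 26, 0 of 11 and 0 of 19 members passed in edgeR, 2, 0 and 1 had an unadjusted p under 0.05, 1, 0 and 0 passed in DESeq2, and 2, 0 and 0 were lower adjusted over the list alone. Ido1 read 79.7 ± 4.52 CPM against 95.8 ± 0.365 (edgeR adjusted p = 0.222), Foxp3 2.34 ± 0.557 against 2.73 ± 0.287 (edgeR adjusted p = 0.810) and Mcpt1 13.3 ± 1.2 against 13.5 ± 7.19 (edgeR adjusted p = 0.989). The same test gave 0.881 for Il10, 0.910 for Tgfb1, 0.754 for Il2ra, 0.899 for Ctla4, 0.696 for Itgae, 0.631 for Aldh1a2, 0.841 for Cd274, 0.521 for Mcpt2 and 0.714 for Cpa3.

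Aqp8 had 104 reads in T-MEM49 and 1 in Sensitized, a ratio of 102 with a 95% exact counting interval of 17.9 to 4072, and Dmrt3 had 62 and 3, a ratio of 20.3 with an interval of 6.63 to 101. Rspo1, a Wnt pathway agonist gene, fell from 4.09 ± 1.09 to 0.797 ± 0.119 CPM. Over all genes, 55 passed, 18 higher and 37 lower in T-MEM49. In simulated data edgeR recovered 24.8%, 60.6% and 79.1% of genes changed 1.5-fold, 2-fold and 4-fold, and 6.79% of its calls were of unchanged genes. With only the compared groups in the fit the count was 5, with no low-count filter 28 and by DESeq2 334. The count was 6 without T-MEM49 replicate 1, 4 without T-MEM49 replicate 2, 419 without Sensitized replicate 1 and 401 without Sensitized replicate 2. Of 19 named genes that passed, 2 passed with either T-MEM49 library left out, Cyp2c55 and Hba-a1. Aqp8, Dmrt3 and Rspo1 reached 0.321, 0.219 and 0.408 in edgeR with a T-MEM49 library left out, and Rspo1 did not pass without Sensitized replicate 2. By camera 11 of 38 lists passed, 0 did with an estimated correlation (5 at an unadjusted p under 0.05) and fry called 6. Without Sensitized replicate 1 the number of lists was 17.

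**Figure D2:**
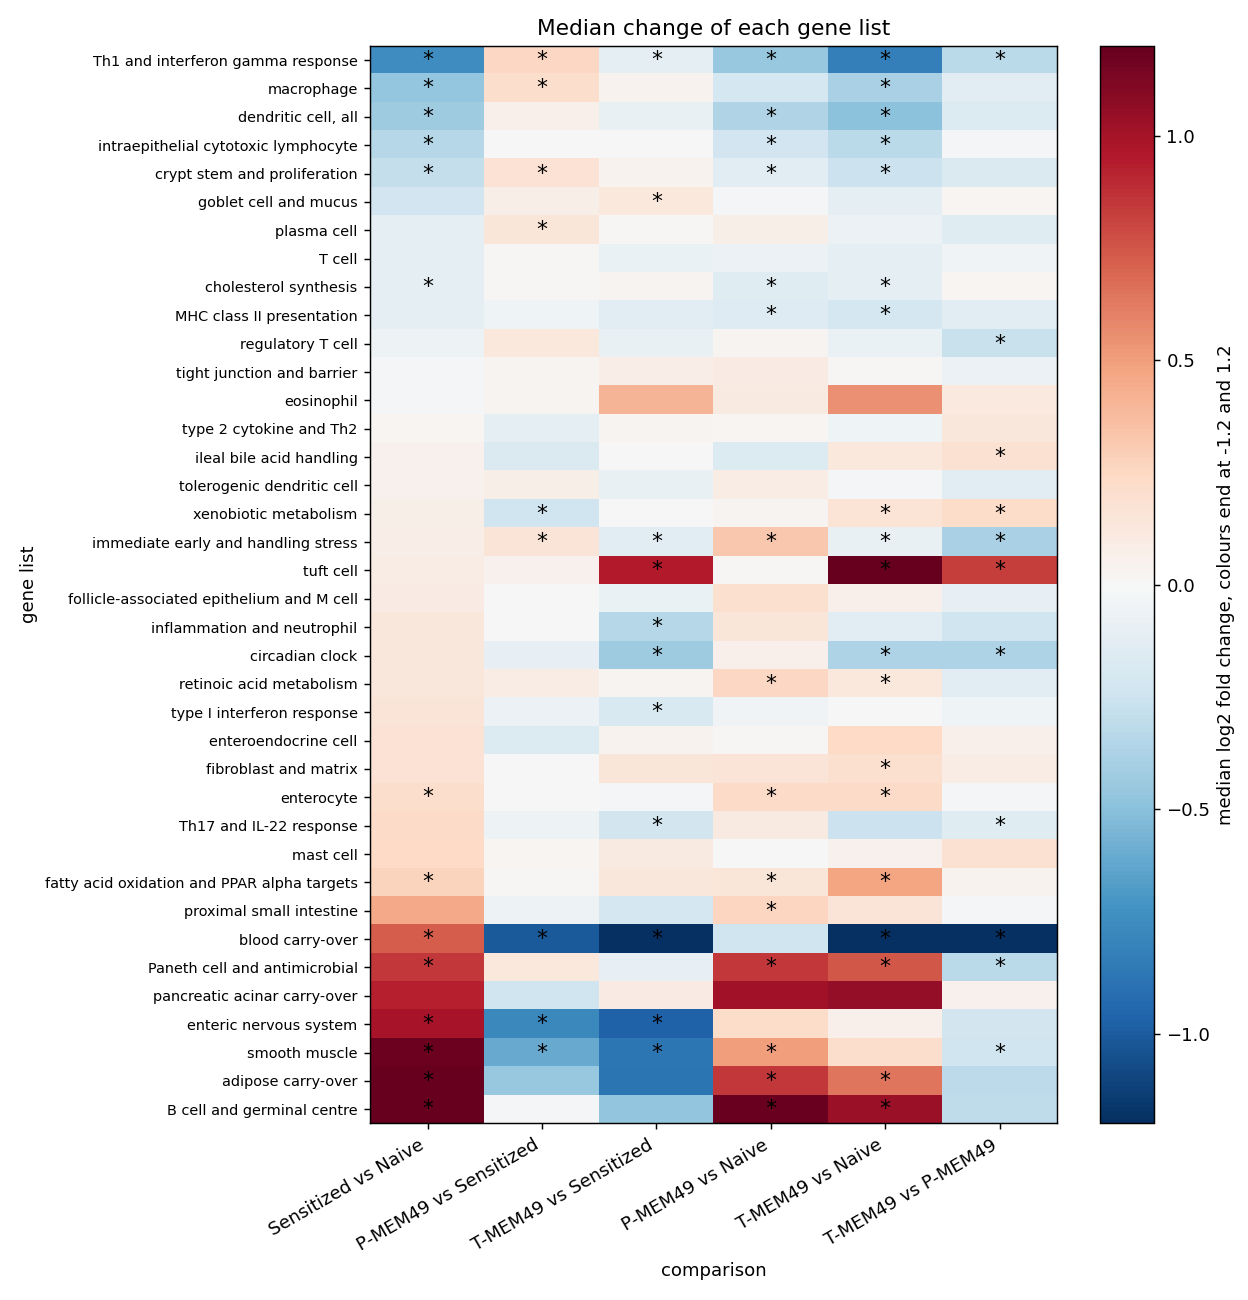
The colour of each cell gives the median log2 fold change of a gene list (vertical axis) in a comparison (horizontal axis), on a scale that ends at -1.2 and 1.2, and a star marks a camera adjusted p under 0.05 with the preset correlation. The interferon gamma list stood at -0.74 in Sensitized against Naive and the tuft cell list at 0.95 in T-MEM49 against Sensitized.

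Both vaccinated groups were also compared with Naive, which asks where they stood relative to mice that were not sensitized. In P-MEM49 the Paneth cell and antimicrobial list was higher than in Naive, with 14 of its 22 tested members higher, 16 adjusted over the list alone (camera adjusted p = 2.22e-18, adjusted p = 0.101 with an estimated correlation), and in T-MEM49 13 of its 22 tested members were higher, 15 adjusted over the list alone (camera adjusted p = 2.71e-11, adjusted p = 0.138 with an estimated correlation). The Th1 and interferon gamma list was lower in both, with 8 of its 27 tested members lower in P-MEM49, 12 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.16e-12, adjusted p = 0.101 with an estimated correlation). In T-MEM49 16 of its 27 tested members were lower, 21 lower and 1 higher adjusted over the list alone (camera adjusted p = 6.10e-20, adjusted p = 0.0778 with an estimated correlation). The B cell list was higher in both, with 1 of its 29 tested members higher in each, Rgs13, and 15 in P-MEM49 and 3 in T-MEM49 adjusted over the list alone. Its camera adjusted p was 7.40e-14 in P-MEM49 (adjusted p = 0.388 with an estimated correlation) and 9.79e-07 in T-MEM49 (adjusted p = 0.485 with an estimated correlation).

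In P-MEM49 the smooth muscle list was 0.50 log2 above Naive with 1 of its 20 tested members higher, Actg2, 6 adjusted over the list alone (camera adjusted p = 4.34e-08, adjusted p = 0.388 with an estimated correlation). In T-MEM49 the tuft cell list was 1.40 above Naive with 4 of its 16 tested members higher (Dclk1, Avil, Rgs13 and Sh2d6), 7 adjusted over the list alone (camera adjusted p = 3.43e-07, adjusted p = 0.146 with an estimated correlation), and the blood list -2.91 with 4 of its 6 tested members lower, the hemoglobin genes, 5 adjusted over the list alone (camera adjusted p = 1.19e-07, adjusted p = 0.146 with an estimated correlation). Hba-a1 stood at -3.89 ± 0.26 log2 relative to Naive. Car1 was lower in P-MEM49 than in Naive (-3.25 ± 0.51). Zfp97 was not listed in Naive and read 2.0 ± 0.286 CPM in P-MEM49 and 1.94 ± 1.13 CPM in T-MEM49. Kremen2 and Nphs1, not listed in Naive, read 0.909 ± 0.0911 and 0.932 ± 0.00972 CPM in P-MEM49. Rgs22 was listed in T-MEM49 alone, at 1.15 ± 0.0795 CPM. Rgs13, a signalling regulator of B and tuft cells, Actg2, Dclk1, Avil and Sh2d6 were named here after their values were seen.

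Against Naive, 242 genes passed edgeR's test in P-MEM49 (151 higher, 91 lower) and 751 in T-MEM49 (380 higher, 371 lower). With only the compared groups in the fit the counts were 503 and 1125, and by DESeq2 552 and 1080. The P-MEM49 count was 84 without Naive replicate 1, 64 without Naive replicate 2, 41 without P-MEM49 replicate 1 and 33 without P-MEM49 replicate 2, and the T-MEM49 count 343 without Naive replicate 1, 204 without Naive replicate 2 and 126 with either T-MEM49 library left out. The 6 genes named by size in P-MEM49, among them Car1, Zfp97, Kremen2 and Nphs1, each lost the call with any of the 4 libraries left out (edgeR adjusted p up to 0.251, 0.0798, 0.156 and 0.152), while Hba-a1 and Zfp97 passed in T-MEM49 in each case and Rgs22 in none (up to 0.283). By camera 15 and 19 of 38 lists passed, 0 and 0 with an estimated correlation (5 and 8 at an unadjusted p under 0.05), and fry called 13 and 21. They included the retinoic acid metabolism list, higher in P-MEM49 and T-MEM49 (2 and 3 of 21 tested members called). The proximal small intestine list was higher in P-MEM49 alone (2 of 12 tested members called), a call that did not hold with some single libraries left out. Lower in both were all dendritic cell genes (1 and 2 of 17) and MHC class II presentation (0 and 4 of 14). The first list in T-MEM49 and the last named lists in P-MEM49 lost their calls with some single libraries left out.

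T-MEM49 and P-MEM49 differ in when the vaccine was given. Hspa1b was lower in T-MEM49 (-3.02 ± 0.14 log2, edgeR adjusted p = 4.92e-05), as was Hba-a1 (-3.56 ± 0.26, edgeR adjusted p = 6.51e-04), and Cyp2c55 was higher (4.72 ± 0.14, edgeR adjusted p = 4.77e-06). The regulatory T cell list was lower in T-MEM49 with a median of -0.27 and 2 of its 26 tested members lower, the same number adjusted over the list alone (camera adjusted p = 0.0180, adjusted p = 0.399 with an estimated correlation). Gzmb (-0.75 ± 0.084) was among those members. Gzmb, Trpm5, Avil, Abcg5, Abcg8, Lyz1 and Reg3g were chosen for naming here after their values were seen, and Foxp3 stood at -0.25 ± 0.29 (edgeR adjusted p = 0.720). The Th1 and interferon gamma list was lower with 6 of its 27 tested members lower, 10 adjusted over the list alone (camera adjusted p = 1.52e-07, adjusted p = 0.194 with an estimated correlation). The tuft cell list was higher with 2 of its 16 tested members higher, Trpm5 and Avil, 5 adjusted over the list alone (camera adjusted p = 9.00e-06, adjusted p = 0.238 with an estimated correlation), and the bile acid handling list with 2 of its 10 tested members higher, the sterol exporter genes Abcg5 and Abcg8, 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0277, adjusted p = 0.264 with an estimated correlation). The Paneth cell list was lower with 2 of its 22 tested members lower, Lyz1 and Reg3g, 6 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0461, adjusted p = 0.447 with an estimated correlation), while the mean of its members was 0.074. Camera gave that list 0.127 without P-MEM49 replicate 2, 0.106 without T-MEM49 replicate 1 and 0.0635 without T-MEM49 replicate 2. Over all genes 364 passed, 181 higher and 183 lower in T-MEM49. With only the compared groups in the fit the count was 2122, with no low-count filter 221 and by DESeq2 710. The count was 42 without P-MEM49 replicate 1, 47 without P-MEM49 replicate 2, 43 without T-MEM49 replicate 1 and 17 without T-MEM49 replicate 2. By camera 11 of 38 lists passed, 0 did with an estimated correlation (7 at an unadjusted p under 0.05) and fry called 10.

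The vaccinated groups were then compared gene by gene. Against Sensitized, 12 genes were called in the same direction in P-MEM49 and T-MEM49: the clock output genes Ciart and Dbp, the muscle genes Des and Acta1, Saa1, the glucose transporter gene Slc2a4, Cd59a, Optc, Shisal1 and Upk3b lower, and Dmrt3 and the calcium-binding protein gene S100g higher. Those outside the fixed naming rule were named after their values were seen. Cyp2c55 and Plb1, a phospholipase gene, were called in opposite directions, Cyp2c55 at -1.37 ± 0.15 and 3.35 ± 0.13 and Plb1 at -1.06 ± 0.17 and 1.42 ± 0.17 log2. Of the genes called in Sensitized against Naive, 110 were called the opposite way in P-MEM49 against Sensitized and 31 in T-MEM49 against Sensitized, Ido1, Gbp2 and Gzmb among the first and Reg3g and Des among the second. Simulated unchanged groups on the same controls gave a mean overlap of 0 in each of the 3 cases. Those groups gave almost no calls, so that overlap says nothing about the shared controls. By chance, independent lists of these lengths would share 0.294, 6.25 and 2.01 genes. Across genes, which are not independent replicates, the fold changes of the 2 vaccinated groups against Sensitized correlated at r = 0.49 against 0.67 in simulation, with a covariance of 0.257 against 0.109, a difference of 0.149. For the reversed comparisons r was -0.54 against -0.61 in P-MEM49 and -0.49 against -0.62 in T-MEM49, and the covariances were -0.344 and -0.301 against -0.108 in both, differences of -0.236 and -0.193. Sensitized was not split, since each part would hold 1 library, so part of each overlap beyond independent lists can come from the shared controls.

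Leaving out single libraries moved these overlaps. The shared count of 12 was 186 without Sensitized replicate 1, 208 without Sensitized replicate 2, 0 without P-MEM49 replicate 2 and 1 without P-MEM49 replicate 1 or either T-MEM49 library. The count of 110 was 49 without Naive replicate 1, 64 without Naive replicate 2, 366 and 417 without Sensitized replicates 1 and 2, and 14 and 13 without P-MEM49 replicates 1 and 2. The count of 31 was 10 and 9 without Naive replicates 1 and 2, 269 and 302 without Sensitized replicates 1 and 2, and 2 with either T-MEM49 library left out.

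**Figure D3:**
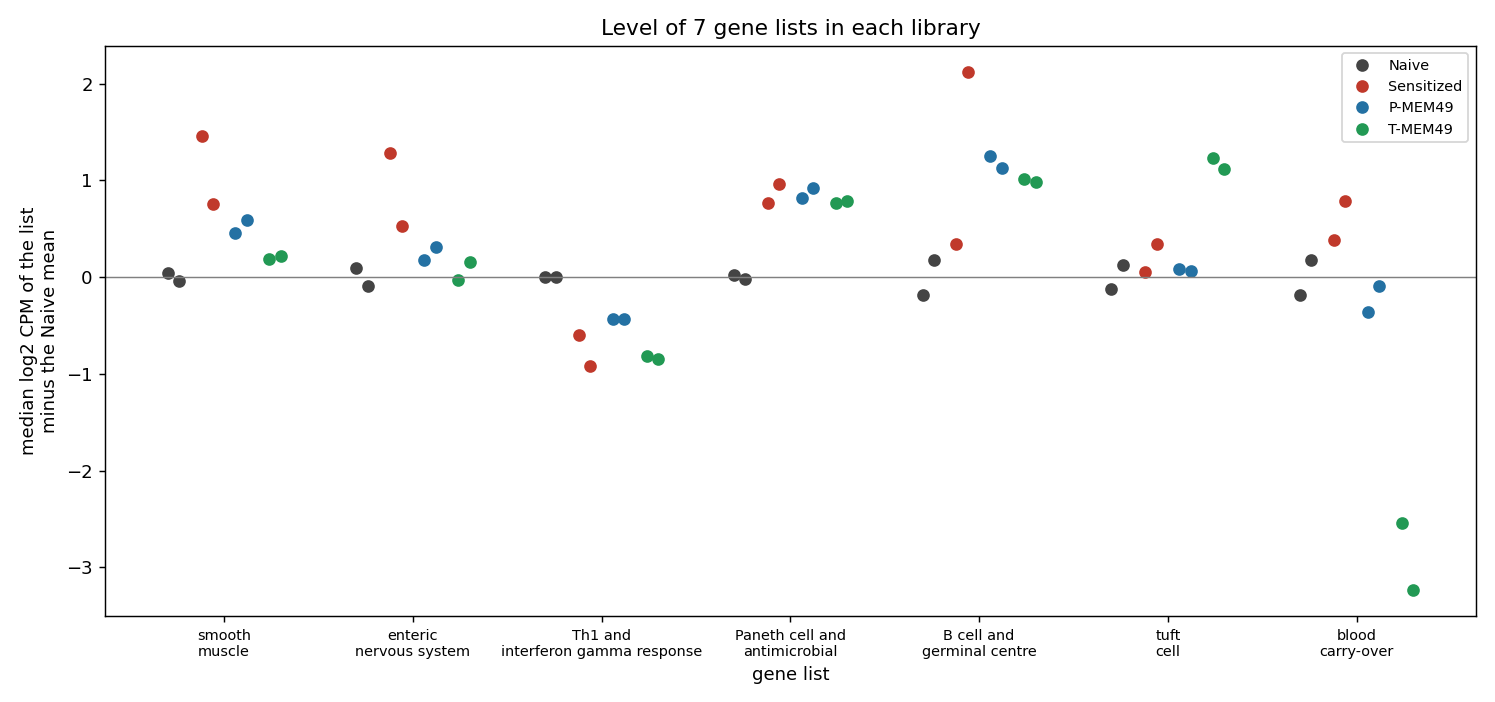
Points give, for each library, the median over the genes of a list (horizontal axis) of log2 CPM minus the Naive mean of each gene (vertical axis, log2), coloured by group. The B cell list lay at 2.12 in Sensitized replicate 2 and 0.34 in replicate 1, and the blood list at -2.54 and -3.24 in the T-MEM49 libraries.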

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

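Of the tests in this part, those of the opposite clock phase and of the immediate early genes were chosen, and their bounds written, after the results they explain were seen; the glucocorticoid, large intestine and interleukin 13 tests were written before their values were seen.

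The effect of vaccination against Sensitized differed between T-MEM49 and P-MEM49 for 29 of the genes reported here that the naming rule gave in those comparisons, and the difference itself was tested with edgeR. Each value is the log2 fold change of T-MEM49 against P-MEM49. Higher in T-MEM49 were Abcc2 (0.52), Aqp8 (6.35), Car1 (5.11), Cyp2c55 (4.72), Cyp3a25 (1.16), Gsdmc2 (2.67), H2-M2 (1.09), Kcnj13 (1.93) and Trpm5 (1.57) (edgeR adjusted p up to 0.0428). Heat shock and stress genes were lower, Hspa1a (-2.94), Hspa1b (-3.02), Hsph1 (-2.70) and Atf3 (-1.70), as were hemoglobin genes, Hba-a1 (-3.56), Hba-a2 (-2.37), Hbb-b1 (-2.51) and Hbb-b2 (-4.22) (edgeR adjusted p up to 0.0230). Also lower were Gbp2 (-0.85), Gzmb (-0.75), Ido1 (-1.25), Ifi202b (-2.31), Irgm1 (-0.76), Irgm2 (-1.04), Rsad2 (-0.81) and Zbp1 (-0.98), together with Reg3g (-1.07) and Usp2 (-0.93) (edgeR adjusted p up to 0.0318). Pclo and Zkscan16 were not listed in P-MEM49 and read 4.14 and 0.587 CPM in T-MEM49 (means), and whether they had no reads in P-MEM49 or a failed estimate is not known. Of the 29 genes, 9 passed without P-MEM49 replicate 1, 12 without P-MEM49 replicate 2, 11 without T-MEM49 replicate 1 and 8 without T-MEM49 replicate 2. The 8 that passed in each of these were Atf3, Cyp2c55, Cyp3a25, Hba-a1, Hspa1a, Hspa1b, Hsph1 and Ido1.

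Of the lists called in P-MEM49 or T-MEM49 against Sensitized, 8 also differed between the 2 groups by camera. The median log2 fold change was -2.44 for blood, -0.37 for the circadian clock, -0.39 for immediate early and stress genes, -0.24 for smooth muscle, -0.32 for Th1 and interferon gamma, -0.14 for Th17 and IL-22, 0.83 for tuft cells and 0.22 for xenobiotic metabolism (camera adjusted p up to 0.0183). None of the 38 lists passed with an estimated correlation in that comparison, where 7 had an unadjusted p under 0.05 by camera. Without T-MEM49 replicate 2 the Th17 list did not pass (camera adjusted p = 0.0825).

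Chaperone genes were higher and the clock output genes Ciart, Dbp and Nr1d1 lower in P-MEM49 than in Sensitized, while the fixed circadian clock list did not pass (camera adjusted p = 0.420; of 18 members 1 was called higher and 3 lower, 4 and 3 adjusted over the list alone). Ciart, Dbp and Nr1d1 were named here after their values were seen. The same genes were called the opposite way in Sensitized against Naive, where no mice were vaccinated: Ciart 0.62, Dbp 0.43, Nr1d1 0.78, Hspa1a -1.39, Hspa1b -1.40 and Hsph1 -1.14 (log2). Of the 18 clock members 7 were called there, and at an unadjusted edgeR p under 0.05 7 were higher and 4 lower. Part of the pattern can thus lie in the shared Sensitized libraries, and collection time was not tested in that comparison. Tissue handling that induces immediate early genes with the chaperones, by at least 1 log2, is argued against. The 16 immediate early genes without the chaperones had a median log2 fold change of 0.057 (SD 0.40 over genes). Of them 10 were above 0, 2 at or above 0.5 and 1 called higher. The median thus lay below the bound of 0.5 by more than this spread. That spread lies between genes and gives no error between pools. Handling that raises chaperones without most immediate early genes stays open and was not tested. Another time of collection stays open and cannot be told apart from an effect of the vaccine, since 5 genes of the opposite clock phase had a median of 0.27, short of the bound of 0.3, at percentile 98.2 of 10000 random groups. In T-MEM49, where the chaperones Hspa1a, Hspa1b and Hsph1 were not higher, these 5 genes had a median of 0.16. A set of 6 clock output genes stood at -0.75 in T-MEM49 and -0.70 in P-MEM49 (medians), so a fall of that size was seen without higher chaperones. The set holds Ciart, Dbp and Nr1d1 and both groups share the Sensitized libraries, so these medians describe the pattern and do not test its cause. Whether higher glucocorticoid signalling contributes stays open. A list of 17 glucocorticoid targets, which left out Fkbp5, Tsc22d3, Sgk1 and Cidec, had a median of 0.11 in P-MEM49 against Sensitized (camera p = 0.0497, p = 0.174 with an estimated correlation). This was a bare pass, in which 0 targets were called by edgeR and 11 were above 0. Its largest change was a fall, of Mt2 (-1.23 ± 0.26), a gene named after its value was seen.

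Car1, Aqp8, Cyp2c55 and Gsdmc2 were higher in T-MEM49 than in Sensitized. Large intestine tissue in the T-MEM49 pools cannot be told apart from a change within the ileum: 13 of 20 other large intestine genes could be tested, with a median log2 fold change of 0.22 (camera p = 0.0435, p = 0.0994 with an estimated correlation), between the bounds of 0.1 and 0.5, and without the Gsdmc genes the median was 0.091 (camera p = 0.488). A type 2 cytokine response of the epithelium is a candidate explanation that fitted its test: 6 of 12 other genes induced by interleukin 13 could be tested and 6 were above 0, with a median of 0.87 (camera p = 2.69e-06, p = 0.0433 with an estimated correlation), though edgeR called 0. Gsdmc3 and Gsdmc4, near copies of Gsdmc2, are in both lists. Without the Gsdmc genes 4 of 9 interleukin 13 genes could be tested, below the minimum size set for the fixed lists. They had a median of 0.72 (camera p = 0.00140, p = 0.0461 with an estimated correlation). These were Pla2g4c (0.95 ± 0.30), Sprr2a2 (0.79 ± 0.21), Sprr2a3 (0.55 ± 0.23) and Sprr2b (0.65 ± 0.82), named after their values were seen. The Sprr2 genes belong to the same family by symbol, and whether they share reads was not tested. They may thus not count as separate evidence. The fixed type 2 cytokine list did not pass in T-MEM49 against Sensitized (median 0.032, camera adjusted p = 0.676). Il13 itself had too few reads to test.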

How the results depend on the processing

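The term for Naive replicate 2 and Sensitized replicate 2, the restriction to genes listed in every library and the voom fit with a weight per group were chosen after the results were seen; the other alternatives were fixed beforehand. The cause of a changed count was not tested, except that a minimum fold change can only lower a count. With a library left out, the shared spread rests on the other pairs, which differ in tightness. Such a count therefore mixes this shift with the values of the library itself. The counts of genes and lists under each alternative that are not given here stayed within 1.5 times the values reported.

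For genes changed in Sensitized against Naive, 1162 became 727 with no filter on low counts, 1912 with the added term, 67 with only the compared groups in the fit, 520 with voom group weights and 393 at a log2 fold change of at least 1. In P-MEM49 against Sensitized, 183 became 101 with no filter, 549 by DESeq2, 31 with only the compared groups and 59 at a log2 fold change of at least 1. In T-MEM49 against Sensitized, 55 became 28 with no filter, 143 with the added term, 334 by DESeq2 and 5 with only the compared groups. Against Naive, the P-MEM49 count of 242 became 552 by DESeq2, 503 with only the compared groups, 619 with voom group weights and 101 at a log2 fold change of at least 1, and the T-MEM49 count of 751 became 1181 with voom group weights and 224 at that fold change. In T-MEM49 against P-MEM49, 364 became 221 with no filter, 740 with the added term, 710 by DESeq2, 2122 with only the compared groups, 1663 with voom group weights and 98 at a log2 fold change of at least 1.

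The number of lists changed was 0 in each of the 6 comparisons by camera with an estimated correlation, with 3, 3, 5, 5, 8 and 7 lists at an unadjusted p under 0.05 in the order above. That run also uses fewer degrees of freedom, so these losses do not measure correlation between members alone. By fry the number of lists was 3 in P-MEM49 against Sensitized and 6 in T-MEM49 against Sensitized, and within 1.5 times the number by camera in the other 4.

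The 12 genes called in the same direction in both vaccinated groups became 86 by DESeq2 and 47 with the added term. The 110 genes reversed in P-MEM49 became 310 by DESeq2, 56 with no filter and 182 with the added term, and the 31 reversed in T-MEM49 became 164 by DESeq2, 16 with no filter and 101 with the added term.

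Over all genes, deviations of equally numbered libraries from their group means correlated at -0.0088 to 0.0643, the highest between Naive and Sensitized. Such a correlation cannot exclude pairing in a subset of genes. Naive replicate 2 and Sensitized replicate 2 stood apart from the other libraries in 87 genes. With the replicate number as a block, the count for T-MEM49 against Sensitized was 26 and the number reversed in T-MEM49 was 16, while the other counts of genes were 1000, 143, 181, 694 and 286 in the order above and changed by less than 1.5 times.

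With each library left out in turn, the numbers of genes changed ranged over 281 to 1722 in Sensitized against Naive, 23 to 583 in P-MEM49 and 4 to 419 in T-MEM49 against Sensitized, 33 to 84 in P-MEM49 and 126 to 343 in T-MEM49 against Naive, and 17 to 47 in T-MEM49 against P-MEM49. The numbers of lists ranged over 7 to 14 in P-MEM49 and 8 to 17 in T-MEM49 against Sensitized. The 3 overlaps ranged over 0 to 208, 13 to 417 and 2 to 302.

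Of 105 calls of named genes over the comparisons, 105 held with DESeq2's size factors, 82 by DESeq2, 83 with the replicate block and 98 with the added term. The sign of each stayed. A gene to which DESeq2 gave no adjusted p was counted as a call that did not hold. Without Naive replicates 1 and 2, 22 and 23 of 60 such calls held, without Sensitized replicates 1 and 2, 79 and 82 of 87, without P-MEM49 replicates 1 and 2, 9 and 9 of 32, and without T-MEM49 replicates 1 and 2, 7 and 6 of 31. The signs that changed belonged to genes that had not passed. The log2 fold change of Mcpt1 in P-MEM49 against Sensitized was -0.0026 with DESeq2's size factors and -2e-04 by DESeq2, and in T-MEM49 against Sensitized it was 0.020 with the replicate block and 0.32 with the added term, which gave Tgfb1 0.38. With a library left out, log2 fold changes in Sensitized against Naive ranged over -0.28 to 0.12 for Foxp3, -0.31 to 0.43 for Il2ra, -0.81 to 0.34 for Mcpt1 and -0.28 to 0.74 for Tgfb1. In P-MEM49 against Sensitized they ranged over -0.064 to 0.15 for Foxp3, -0.45 to 0.69 for Mcpt1 and -0.16 to 0.86 for Tgfb1. In T-MEM49 against Sensitized they ranged over -0.45 to 0.27 for Cd274, -7e-04 to 0.98 for Cpa3, -0.35 to 0.056 for Ctla4, -0.58 to 1.60 for Il10, -0.71 to 0.10 for Il2ra, -0.49 to 0.67 for Mcpt1 and -0.55 to 0.48 for Tgfb1.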

Other observations

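The comparison of the 2 Sensitized libraries for nerve genes was chosen after the result was seen, while the fit with the smooth muscle level was written before its values were seen.

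More muscle wall in the Sensitized tissue pieces is a candidate explanation for the higher smooth muscle and nerve genes in Sensitized. Within the Sensitized pair, the library with more smooth muscle mRNA (median of gene differences 0.64 log2) also had more nerve mRNA, with the same measure at 0.62 and 15 of 16 genes higher. A change in the animals, such as muscle growth after sensitization, stays open and was not tested. The muscle share was also tested as the whole cause of the lower interferon gamma list. With the smooth muscle level of each library as a covariate, the list's median log2 fold change was -1.12 against -0.74 without it. The median of its members' single SEs was 0.33. The covariate's slope rests mostly on the Sensitized pair, whose smooth muscle medians lay 1.45 and 0.75 log2 above the Naive mean. This pair differs in other lists too, so the fit cannot decide whether muscle share explains the fall. In that fit 11 of 27 members were called lower by edgeR (camera adjusted p = 1.63e-08) and 635 genes in all.

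Other differences lay within the Sensitized pair, whose sham treatment was PBS or mock plasmid, unlabelled per library. Replicate 1 stood at -1.71 log2 (median) against replicate 2 in the B cell list and -1.68 in the adipose list. Genes without a symbol took 1.31% of the reads in Naive replicate 2 and 1.43% in Sensitized replicate 2, and 0.550% to 0.790% in the other 6 libraries. Of the 87 genes in which these 2 libraries stood apart, 36 were higher and 51 lower in them.

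Some genes were missing from 2 libraries alone. Of 27 genes unlisted in exactly 2 libraries and with at least 20 estimated reads in each of the others, 4 were unlisted in both libraries of 1 group, and 4 of the 28 possible pairs of libraries are pairs within a group. Slc4a1, a red cell membrane gene below the expression filter, had 61.7 estimated reads in Sensitized replicate 2 and 4.39 in Sensitized replicate 1, and was not listed in the other 6 libraries. Il4, Il5 and Il13 had under 4 estimated reads in every library.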
